A study of Mus musculus with 12 samples.

How the data were processed

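RNA was measured in 12 whole-kidney libraries of mice on a C57BL/6J background, in 4 groups of 3, wild type and tubule-specific Arntl knockout at ZT4 and ZT16. Per the labels' protocols, 500 ng of RNA went into TruSeq stranded mRNA libraries. Per the submitters' processing notes, the deposited read counts per gene were made by trimming with cutadapt 1.2.1, aligning to GRCm38 with TopHat2 2.0.9 and counting with HTSeq 0.5.4p3, and the authors then used edgeR and limma in R 3.1.1, whose output was not used here. The counting mode, strand setting and annotation release are not given in the sources used here, nor is the sex of the mice.

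Each file held 38924 gene IDs, of which GENCODE M21 named 37607. The other 1317 kept their IDs, and 6 symbols belong to more than 1 ID. Lines that HTSeq adds for unassigned reads were left out of library sizes and tests: no feature 3.50% to 5.96%, ambiguous 0.411% to 0.534% and not uniquely aligned 30.8% to 43.0% of each library. Gene counts summed to 33403009, 27139383 and 31299052 in WT ZT4 replicates 1, 3 and 5, to 33357778, 37648890 and 25628887 in KO ZT4 replicates 2, 4 and 6, to 31806844, 38043491 and 35363718 in WT ZT16 replicates 1, 3 and 5, and to 35638932, 34338965 and 25904425 in KO ZT16 replicates 2, 4 and 6. The 10 most abundant genes took 17.7% to 30.9% of the counts.

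Genes were filtered with filterByExpr over the 4 groups, which left 16150, scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood in 1 fit of all 12 libraries (8 residual degrees of freedom, common dispersion 0.01785), in R 4.3.3. Adjusted p is Benjamini-Hochberg over all tested genes, and a gene is called at adjusted p under 0.05. The 6 comparisons were knockout against wild type at ZT4, at ZT16 and averaged over both, ZT16 against ZT4 in each genotype, and the interaction. Log2 CPM used a prior count of 2. Errors are SE of the fitted log2 fold change, or SD of CPM over 3 libraries where said. Chi-square between 2 libraries used genes with a summed count of at least 20.

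For gene lists, 42 were fixed before the data were examined, 26 of pathways and 16 of cell type markers and checks. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which treats genes of a list as nearly independent, and adjusted over the 42 lists. Camera with a correlation estimated from the libraries and fry were alternatives. The text gives members passing over all genes and with adjusted p computed over the list alone. Some lists share members, so their calls are not separate evidence.

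Genes named in the report followed a rule fixed before their values were seen: Arntl and the clock lists, the 10 largest rises and falls per comparison among called genes with a mean of at least 5 CPM, no overlap of library values and an established symbol, and up to 4 genes with the smallest adjusted p per list. Of 413 results this rule allowed and called, 247 kept their call when each library was left out (45 of 67 at ZT4, 52 of 70 at ZT16, 83 of 102 over both, 37 of 83 and 27 of 88 between the times in wild type and knockout, 3 of 3 for the interaction). The text names mostly those, a narrowing made after their values were seen, so it does not show how stable called genes are in general. Vim over both times and Egr2 for the interaction fall outside the rule and were chosen after their values were seen.

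Of 113 named genes, 17 share exonic bases with another tested gene and 5 share at least 10% with 1 gene: Arg2 with Vti1b (20.0%), Dbp with Sphk2 (18.0%), Csf1r with Hmgxb3 (15.1%) and Acaa1b with Dlec1 (11.4%) on opposite strands, and Nat8f5 with Nat8f6 (13.7%) on the same strand. Without a stated strand setting their reads cannot be told apart. Values of Cyp2a4 and Cyp2a5, Cyp4a12a, Hspa1a and Hspa1b, Serpina1d, Ces1d and Ces1g, and Nat8f5 are uncertain too, since close paralogs can share reads.

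The pipeline was tested on simulated data with the dispersion of each gene in these libraries, 15924 genes tested and 100 changed genes per fold. Genes were drawn independently with the same dispersion in every library, so the simulation held no outlying library and no variation shared between genes. At ZT4 edgeR recovered 90% of genes changed 2-fold and 39% of those changed 1.5-fold, with 6 unchanged genes called. DESeq2 1.42.0 recovered 93% and 64% with 38 unchanged genes called. For the interaction edgeR recovered 50% and 5%, so a low count there does not show that few genes differ. Between the simulated wild-type groups, where no gene was changed, edgeR and limma voom called 0 and DESeq2 4 genes. These values do not measure error control in data with an outlying library or variation shared between genes.

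Alternatives chosen before the data were examined were RLE and upper-quartile scaling, no filter, a mean of at least 5 CPM, DESeq2, limma voom, adjusted p under 0.01, only the 6 libraries compared, each library of the compared groups left out, and the replicate number as a block. Added after seeing the data were each library outside the compared groups left out, offsets for exonic length and GC content (known for 99.05% of tested genes), KO ZT16 replicate 2 and WT ZT16 replicate 5 left out together, the offsets with KO ZT16 replicate 2 left out, and limma voom with sample quality weights. No scaling moved the median of all genes by over 0.05. Transcript sequences served for GC content. Results on 2 single genes are not reported here, 1 of them among the 3 called for the interaction.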

Results

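Whole kidneys of mice were profiled by poly(A)-selected, strand-specific RNA sequencing to ask what the loss of the clock transcription factor BMAL1, the product of Arntl, from renal tubule cells changes in kidney gene expression in the light and in the dark. Doxycycline, which switches on a Cre recombinase expressed under the Pax8 tubule promoter in this model, was given in the drinking water at 2 mg/ml for 2 weeks from 8 weeks of age. Kidneys of knockout mice and wild-type littermates were taken at zeitgeber time 4 (ZT4), 4 h after lights on, and at ZT16, 4 h into the dark phase of a cycle of 12 h light and 12 h dark. The 12 libraries formed 4 groups of 3 libraries each, wild type (WT) and knockout (KO) at each time. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. Counts assigned to genes ranged from 25628887 to 38043491 per library, on 19624 to 20558 genes with at least 1 count.

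The deleted gene was examined first. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126 on the plus strand, GRCm38) had 20.01, 15.26 and 13.82 CPM (counts scaled to library size) in WT ZT4 replicates 1, 3 and 5, and 15.95, 14.39 and 16.20 in KO ZT4 replicates 2, 4 and 6. At ZT16 it had 10.52, 8.63 and 11.03 CPM in WT replicates 1, 3 and 5, and 12.28, 13.36 and 15.01 in KO replicates 2, 4 and 6. Its log2 fold change in the libraries labelled knockout was -0.08 ± 0.14 (SE) at ZT4 (adjusted p = 0.777) and 0.43 ± 0.15 at ZT16 (adjusted p = 0.151), n = 3 against 3 each. Arntl at ZT16 passed the test without KO ZT16 replicate 2 (0.49, adjusted p = 0.024), and over its alternatives its adjusted p ranged from 0.0153 to 0.422. The ZT4 value turned to 0.10 without WT ZT4 replicate 1. These counts add up all exons of the gene and all cell types of the kidney, and the exons removed are not stated, so they do not check the labels, and every direction below rests on the labels.

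Several known partners and targets of BMAL1 differed widely between the libraries labelled knockout and wild type, while others, such as Clock, Per1 and Usp2, overlapped at ZT4. Nr1d1 and Nr1d2, which encode the repressors REV-ERBα and REV-ERBβ, fell from 60.1 ± 8.49 (SD, n = 3) to 16.2 ± 2.82 CPM and from 105.4 ± 11.6 to 26.4 ± 0.616 CPM at ZT4. Dbp, a clock output factor, fell from 28.6 ± 4.55 to 9.70 ± 2.36 CPM. Npas2, which encodes a partner of BMAL1 related to CLOCK, rose from 9.77 ± 1.71 to 45.2 ± 0.138 CPM at ZT4 and from 2.94 ± 0.401 to 33.6 ± 7.86 CPM at ZT16. Cry1, which encodes a repressor of BMAL1 and CLOCK, rose from 3.67 ± 0.635 to 25.8 ± 2.27 CPM at ZT4 and from 16.6 ± 1.70 to 28.3 ± 3.86 CPM at ZT16. All these differences passed the quasi-likelihood test described with the comparisons.

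**Figure D1:**
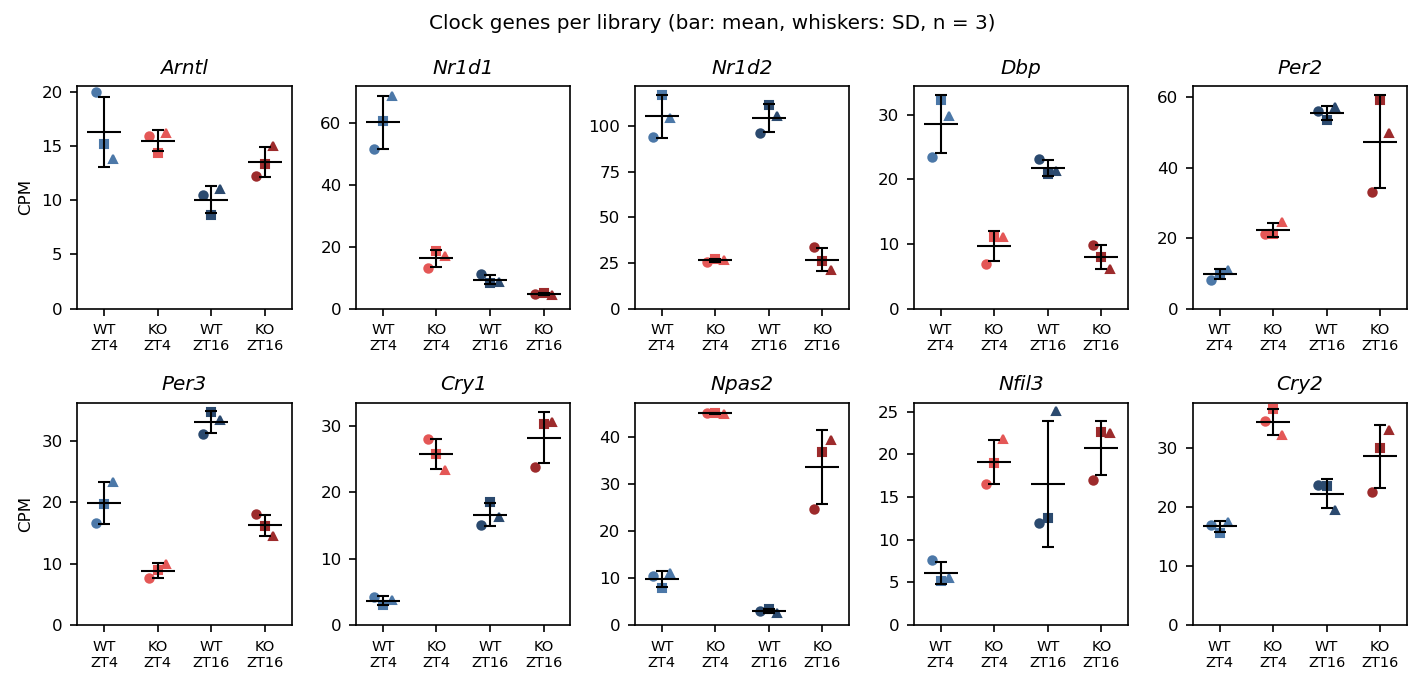
CPM (y axis, one scale per gene) of 10 clock genes in the 12 libraries, by genotype and time (x axis), with each point a library, the bar the group mean and the whiskers the SD (n = 3). Arntl overlaps between genotypes at ZT4, Nr1d1, Nr1d2, Dbp and Per3 lie lower in every knockout library than in the wild-type libraries of the same time, and Npas2 and Cry1 lie higher.

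One library stood apart from its replicates. On the first principal component of log2 CPM, which held 46.7% of the variance, KO ZT16 replicate 2 lay at 43.0 and KO ZT16 replicates 4 and 6 at -9.74 and -11.8. It was not extreme among all libraries, since WT ZT16 replicates 1, 3 and 5 lay at 29.8, 25.1 and 49.0. WT ZT4 replicates 1, 3 and 5 lay at -1.67, 2.83 and -19.1, and KO ZT4 replicates 2, 4 and 6 at -34.6, -37.6 and -35.3. Mitochondrially encoded genes took 22.3% of the counts in KO ZT16 replicate 2 against 14.1% and 14.0% in replicates 4 and 6. The share was 12.6% to 12.8% in KO ZT4, 16.3% to 18.0% in WT ZT4, 18.7% and 18.8% in WT ZT16 replicates 1 and 3, and 22.4% in WT ZT16 replicate 5. The chi-square per degree of freedom between counts of KO ZT16 replicate 2 and replicates 4 and 6 was 191 and 169. Between replicates 4 and 6 it was 4.72, and 5.60 to 45.2 between replicates of the other groups, where counting noise alone gives about 1.

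**Figure D2:**
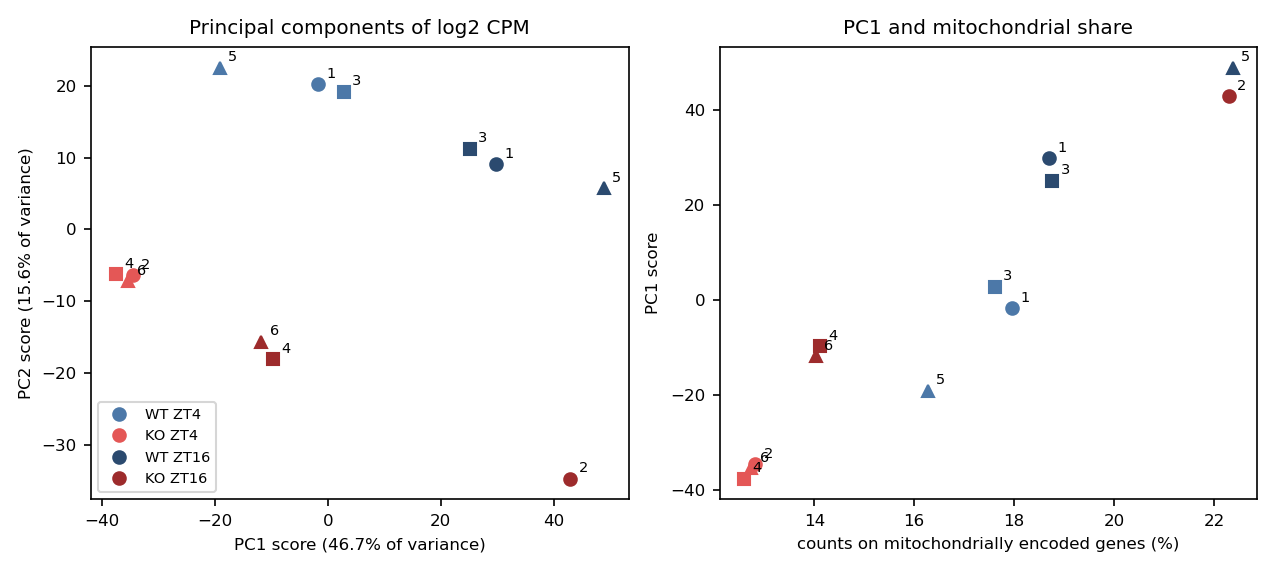
Left, scores of the 12 libraries on the first and second principal components of log2 CPM (x and y axis). Right, the score on the first component (y axis) against the percentage of counts on mitochondrially encoded genes (x axis), with numbers giving the replicate. KO ZT16 replicate 2 lies at 22.3% and a score of 43.0. KO ZT16 replicates 4 and 6 lie at 14.1% and 14.0% and scores of -9.74 and -11.8, and WT ZT16 replicates 1, 3 and 5 at scores of 29.8, 25.1 and 49.0.

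The knockout was compared with wild type at ZT4 to find the effect of tubular BMAL1 loss in the light phase. Genes that rose included Fgg, a chain of the clotting protein fibrinogen (8.41-fold, log2 fold change 3.07 ± 0.19 SE), Loxl4, a collagen-crosslinking enzyme (2.95 ± 0.19), the water channel gene Aqp8 (2.93 ± 0.27) and Cry1 (2.80 ± 0.15). Col6a6, a collagen chain (2.62 ± 0.20), Slc7a12, an amino acid transporter (2.62 ± 0.25), Arg2, which encodes mitochondrial arginase (2.35 ± 0.17), and Bhmt, which remethylates homocysteine with betaine (2.28 ± 0.23), also rose. Genes that fell included the cytochrome P450 gene Cyp4a12a (-2.97 ± 0.35), Alb, the gene of serum albumin (-2.96 ± 0.36), Cyp2a5 (-2.93 ± 0.34), the carboxylesterase genes Ces1g (-2.61 ± 0.18) and Ces1d (-2.30 ± 0.23), and Cyp2a4 (-2.29 ± 0.13). Nat8f5, an N-acetyltransferase family member (-2.23 ± 0.30), Serpina1d, of the alpha-1-antitrypsin family (-2.15 ± 0.27), and Angptl7 (-2.06 ± 0.25) fell as well. Adjusted p ran from 2.04e-06 to 0.00112 over these genes (n = 3 against 3, edgeR quasi-likelihood).

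Among the clock genes at ZT4, 4 of the 6 tested genes of the ROR-element (RORE) list, which REV-ERBs repress, rose and none fell (4 and 0 adjusted over the list alone). Npas2 rose by 2.21 ± 0.17 and Nfil3 by 1.64 ± 0.27. This list was called higher by camera (adjusted p = 4.4e-33) and also with an estimated correlation (adjusted p = 0.00161). Of the 14 tested E-box genes, which BMAL1 and CLOCK bind directly, 6 fell and 2 rose (6 and 3 over the list alone). Nr1d2 fell by 2.00, Nr1d1 by 1.89, Dbp by 1.56 and Per3 by 1.17, while Per2 (2.29-fold, SE of log2 0.18) and Cry2 (2.06-fold, SE of log2 0.13), both repressors of BMAL1, rose. The E-box list was called lower (adjusted p = 2.52e-05, or adjusted p = 0.317 with an estimated correlation).

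Metabolic and transport lists were called at ZT4, and each call in this paragraph was lost with an estimated correlation. In the fatty acid oxidation list 11 of 38 tested genes fell and none rose (20 fell and 2 rose adjusted over the list alone), among them Cpt2 (-0.57 ± 0.06) and Slc25a20 (-0.74 ± 0.09), which carry acyl groups into mitochondria, and Acot1 (-0.81 ± 0.11), an acyl-CoA thioesterase. Camera called it lower (adjusted p = 5.19e-13, or adjusted p = 0.0592 with an estimated correlation). In the xenobiotic list 10 of 32 fell and none rose (14 and 2 over the list alone), including Cyp2e1 (-0.87 ± 0.11) and Cyp4b1 (-0.69 ± 0.11), with camera adjusted p = 5.19e-13 (adjusted p = 0.109 with an estimated correlation). Of 20 organic ion transporters 3 fell and 1 rose (6 and 2 over the list alone). Slc22a8, the organic anion transporter OAT3, was at -0.93 ± 0.11, the carnitine transporter Slc22a5 at -0.86 ± 0.09, and the drug efflux pump Abcb1b rose by 1.05 ± 0.16. Camera adjusted p was 0.000246 (adjusted p = 0.109 with an estimated correlation). Of 19 oxidative stress genes 3 fell (5 over the list alone), including Hmox1, haem oxygenase 1 (-0.84 ± 0.11), and Cat, catalase (-0.49 ± 0.07), with camera adjusted p = 0.000973 (adjusted p = 0.0592 with an estimated correlation). Of 10 androgen-dependent kidney genes 4 fell and none rose (6 and 1 over the list alone, camera adjusted p = 4.86e-07, or adjusted p = 0.197 with an estimated correlation). Cyp2e1, Cyp4b1 and Cyp7b1 are in both this list and the xenobiotic list. Slc22a7 and Slco1a1 are also organic ion transporters, and Acsm3 is also in the fatty acid oxidation list.

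Other genes and lists were also called at ZT4. The phosphate and divalent ion list was called higher (adjusted p = 0.00667, or adjusted p = 0.543 with an estimated correlation), with 2 of 22 genes rising (3 over the list alone), led by the phosphate cotransporter gene Slc34a2 (1.70 ± 0.19). Intercalated cell markers were called higher with 2 of 11 rising (4 over the list alone, adjusted p = 0.00667, or adjusted p = 0.503 with an estimated correlation). No member of the heat shock list passed the test, over all genes or over the list alone, though camera called it lower (median -0.25, adjusted p = 0.006, or adjusted p = 0.503 with an estimated correlation). Nuclear oxidative phosphorylation genes (median -0.23) and mitochondrially encoded mRNAs (median -0.74) were called lower with no member passing over all genes, and 0 and 1 over the lists alone (adjusted p = 0.00391 and 0.000106). With an estimated correlation adjusted p was 0.711 and 0.496, and with length and GC offsets the first lost its call (adjusted p = 0.127). The nuclear receptor gene Ppard (1.94 ± 0.27), the fibrinogen gene Fgb (1.79 ± 0.26), the immediate early gene Ier5 (0.99 ± 0.14) and the vasopressin receptor gene Avpr1a (0.73 ± 0.12) rose, and Havcr1, a marker of proximal tubule injury, fell by 1.71.

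In all, 531 of 16150 tested genes passed at ZT4 (263 higher, 268 lower; 2955 at an unadjusted p under 0.05), with a median absolute log2 fold change of 0.73, and 161 of them at least 2-fold (82 up, 79 down). Library values of the genotypes did not overlap for 6091 genes (37.7%, where chance gives 10%). Here and below the chance share holds for each gene alone. Genes that vary together across libraries can move the share far from it, so a larger share does not by itself show an effect of genotype or time. Loadings on the first principal component had Spearman correlations of -0.347 with exonic length and -0.355 with GC content (protein-coding genes). The count was 248, 232, 251, 228 and 237 without WT ZT4 replicate 1 or 3 or KO ZT4 replicate 2, 4 or 6, in that order, and 2503 without KO ZT16 replicate 2, which enters the shared spread. Camera also called 7 lists that 1 left-out library ended. Without WT ZT4 replicate 1 immediate early genes, cell cycle, interferon and macrophage lists had adjusted p = 0.0856, 0.0589, 0.264 and 0.169. Without WT ZT4 replicate 3 tubular injury and distal convoluted tubule markers had 0.0963 and 0.111, the median of the former turning from -0.15 to 0.07. Without WT ZT4 replicate 5 tubular injury and S3 proximal tubule markers had 0.139 and 0.084. Without KO ZT4 replicate 2 cell cycle, interferon and S3 markers had 0.0555, 0.144 and 0.115. Without KO ZT4 replicate 6 immediate early and distal convoluted tubule lists had 0.379 and 0.111, and without KO ZT16 replicate 2 cell cycle had 0.0559. With an estimated correlation all 7 lost the call. Immediate early, cell cycle, interferon and macrophage lists had adjusted p = 0.581, 0.372, 0.581 and 0.577, and tubular injury, distal convoluted tubule and S3 lists 0.577, 0.55 and 0.317.

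The same comparison at ZT16 gave the effect in the dark phase. Aqp8 rose 13.8-fold (3.79 ± 0.31), Npas2 11.4-fold (3.51 ± 0.19), Col6a6 10.6-fold (3.40 ± 0.22), Loxl4 10.2-fold (3.35 ± 0.19) and Fgg 9.67-fold (3.27 ± 0.19). Ppard (2.83 ± 0.28), Bhmt (2.80 ± 0.25), the fibrinogen genes Fga (2.37 ± 0.24) and Fgb (2.33 ± 0.25), Arg2 (2.37 ± 0.17) and Slc7a12 (2.35 ± 0.24) also rose. Cyp2a5 (-3.20 ± 0.33), Nat8f5 (-2.55 ± 0.28), Alb (-2.55 ± 0.34), Ces1d (-2.51 ± 0.23), Angptl7 (-2.44 ± 0.24), Cyp2a4 (-2.30 ± 0.13) and Cyp4a12a (-2.22 ± 0.34) fell. So did Egr2, an immediate early transcription factor gene (-2.75 ± 0.43), and Angptl4, an inhibitor of lipoprotein lipase (-2.05 ± 0.35). Adjusted p ran from 1.39e-06 to 0.0055 over these genes (n = 3 against 3).

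At ZT16 7 of the 14 E-box genes fell and none rose (9 and 1 over the list alone). Nr1d2 was at -1.96 ± 0.15, Dbp at -1.45 ± 0.20, Per3 at -1.03 ± 0.13, Nr1d1 at -0.97 ± 0.17, the cell cycle kinase gene Wee1 at -0.97 ± 0.15 and Tef, a relative of Dbp, at -0.60 ± 0.09. Of the 6 RORE genes 4 rose and none fell (4 and 1 over the list alone), with Cry1 at 0.76 ± 0.13. Camera called E-box genes lower (adjusted p = 1.12e-15) and RORE genes higher (1.09e-10), and with an estimated correlation too (adjusted p = 0.0459 and 0.0399).

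Fatty acid oxidation genes were called lower at ZT16 with 10 of 38 falling and none rising (19 and 2 over the list alone, adjusted p = 1.16e-14, and adjusted p = 0.0399 with an estimated correlation). Examples were Acaa1b, a peroxisomal thiolase (-1.16 ± 0.14), Slc25a20 (-0.90 ± 0.09) and Cpt2 (-0.56 ± 0.06). Of 19 oxidative stress genes 4 fell (4 over the list alone), including Hmox1 (-0.72 ± 0.11) and Cat (-0.46 ± 0.07), with camera adjusted p = 0.000508, and adjusted p = 0.0399 with an estimated correlation. In the xenobiotic list 11 of 32 fell and 1 rose (14 and 2 over the list alone, adjusted p = 6.19e-14, or adjusted p = 0.0735 with an estimated correlation), with Cyp2e1 at -0.89 ± 0.11. Slc22a5 (-1.01 ± 0.09) and Slc22a8 (-0.80 ± 0.11) fell and Abcb1b (1.02 ± 0.16) rose among the organic ion transporters. Of 18 heat shock genes 5 fell (6 over the list alone, camera adjusted p = 1.22e-07, or adjusted p = 0.186 with an estimated correlation), including the chaperone genes Hspa1b (-1.30 ± 0.23) and Dnaja1 (-0.53 ± 0.10). Of 20 immediate early genes 4 fell (10 over the list alone, adjusted p = 1.22e-07, or adjusted p = 0.331 with an estimated correlation).

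Single genes of amino acid and sterol metabolism also changed at ZT16. Camera did not call the amino acid list there, and its call of cholesterol synthesis was lost without KO ZT16 replicate 2 (adjusted p = 0.178). Ddc, which makes dopamine from L-DOPA, rose by 1.44 ± 0.10, and the glutamine synthetase gene Glul (-0.72 ± 0.10) and Asl, argininosuccinate lyase (-0.48 ± 0.08), fell. Idi1, an enzyme of sterol synthesis, rose by 0.94 ± 0.14 while Insig1, which holds back sterol synthesis, fell by 0.92. Slc34a2 (1.45 ± 0.20) and Avpr1a (0.97 ± 0.12) rose. The phosphate and divalent ion list had 2 of 22 genes rising and none falling (4 and 1 over the list alone, camera adjusted p = 0.0013, or adjusted p = 0.465 with an estimated correlation). Androgen-dependent genes had 3 of 10 falling and 1 rising (4 and 1 over the list alone, adjusted p = 0.000734, or adjusted p = 0.413 with an estimated correlation).

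At ZT16 651 genes passed (335 higher, 316 lower; 2591 at an unadjusted p under 0.05), with a median absolute log2 fold change of 0.76, and 121 rose and 95 fell at least 2-fold. Library values of the genotypes did not overlap for 2563 genes (15.9%, chance 10%). The count was 421, 380, 389 and 384 without WT ZT16 replicate 3 or 5 or KO ZT16 replicate 4 or 6, in that order, and 5099 without KO ZT16 replicate 2. A fit of only these 6 libraries called 200 genes and lost Cry1, Abcb1b, Asl, Hspa1b, Dnaja1 and Cat (adjusted p 0.0515 to 0.135), each of which passed in its other alternatives at 0.05.

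Camera also called 8 lists at ZT16 that 1 left-out library ended. Without KO ZT16 replicate 2 organic ion transporters (1 of 20 rose and 3 fell), cholesterol synthesis, tubular injury and macrophage lists had adjusted p = 0.278, 0.178, 0.112 and 0.106, and the tubular injury median turned from 0.03 to -0.10. Without WT ZT16 replicate 1 organic ion transporters, interferon and macrophage lists had 0.127, 0.294 and 0.123, and without WT ZT16 replicate 3 distal convoluted tubule markers had 0.11. Oxidative phosphorylation, mitochondrially encoded and interferon lists had 0.0926, 0.147 and 0.0725 without WT ZT16 replicate 5. Without KO ZT16 replicate 4 oxidative phosphorylation, mitochondrially encoded, interferon, distal convoluted tubule and macrophage lists had 0.361, 0.113, 0.246, 0.105 and 0.251. Without KO ZT16 replicate 6 the first 2 of these had 0.495 and 0.172. The oxidative phosphorylation median turned from -0.11 to 0.01 and 0.02 without KO ZT16 replicate 4 or 6. With an estimated correlation all 8 lost the call. Organic ion transporters, cholesterol synthesis, tubular injury and macrophage lists had adjusted p = 0.407, 0.413, 0.465 and 0.65. Interferon, distal convoluted tubule, oxidative phosphorylation and mitochondrially encoded lists had 0.679, 0.493, 0.804 and 0.65.

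Averaged over both times, the comparison asked which genes differed in the mean of the genotype effects at ZT4 and ZT16, from 6 libraries against 6. A gene changed mainly at 1 time can also pass, as Cry1 did (2.80 at ZT4 and 0.76 at ZT16). Aqp8 (3.36 ± 0.20), Fgg (3.17 ± 0.14), Loxl4 (3.15 ± 0.13), Npas2 (2.86 ± 0.13), Slc7a12 (2.49 ± 0.17), Ppard (2.39 ± 0.20) and Arg2 (2.36 ± 0.12) rose, and Alb (-2.75 ± 0.25), Cyp4a12a (-2.59 ± 0.24), Ces1d (-2.41 ± 0.16) and Cyp2a4 (-2.30 ± 0.09) fell, with adjusted p from 7.24e-08 to 2.42e-05. Ppard (ENSMUSG00000002250) lies on chromosome 17, 28232700 to 28301474, plus strand. The fibrinogen genes Fgg (ENSMUSG00000033860, chromosome 3, 83007724 to 83015049), Fga (83026076 to 83033627) and Fgb (83040141 to 83049863) lie side by side.

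The clock lists moved apart over both times. Of 6 RORE genes 5 rose (5 over the list alone, camera adjusted p = 4.26e-24, and adjusted p = 0.00778 with an estimated correlation), including Cry1 (1.78 ± 0.10) and Nfil3 (0.99 ± 0.18). Of 14 E-box genes 7 fell and 2 rose (8 and 3 over the list alone, adjusted p = 2.81e-11, or adjusted p = 0.101 with an estimated correlation). Nr1d2 was at -1.98 ± 0.10, Dbp at -1.51 ± 0.14, Nr1d1 at -1.43 ± 0.11 and Per3 at -1.10 ± 0.10, against Cry2 at 0.70 ± 0.09.

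Lists of fatty acid use and defence against oxidants were called lower over both times. In the fatty acid oxidation list 22 of 38 fell and 2 rose (27 and 2 over the list alone; median -0.31, adjusted p = 8.66e-16, and adjusted p = 0.0347 with an estimated correlation). Slc25a20 (-0.82 ± 0.06), Acot1 (-0.72 ± 0.08), Acadl, a long-chain acyl-CoA dehydrogenase gene (-0.66 ± 0.06), and Cpt2 (-0.56 ± 0.05) were among them. Of 19 oxidative stress genes 6 fell and none rose (9 and 0 over the list alone, adjusted p = 0.000237, and adjusted p = 0.0347 with an estimated correlation). Hmox1 was at -0.78 ± 0.08, Cat at -0.47 ± 0.05, superoxide dismutase Sod1 at -0.32 ± 0.06 and sulfiredoxin Srxn1 at -0.31 ± 0.06. Of 32 xenobiotic genes 15 fell and 2 rose (19 and 3 over the list alone, adjusted p = 1.75e-15, or adjusted p = 0.0674 with an estimated correlation). Of 20 organic ion transporters 6 fell and 1 rose (6 and 2 over the list alone, adjusted p = 0.00161, or adjusted p = 0.175 with an estimated correlation). Slc22a5 (-0.93 ± 0.07), Slc22a8 (-0.87 ± 0.08) and Abcb1a (-0.84 ± 0.11) fell while Abcb1b (1.03 ± 0.12) rose. Abcb1a and Abcb1b both encode P-glycoprotein.

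Mitochondrial lists were called lower over both times. Of 70 nuclear oxidative phosphorylation genes 2 fell (0 over the list alone; median -0.16, adjusted p = 0.0017, or adjusted p = 0.79 with an estimated correlation, and adjusted p = 0.0809 with length and GC offsets). Of 11 mitochondrially encoded mRNAs 1 fell (8 over the list alone; median -0.56, adjusted p = 0.000687, or adjusted p = 0.494 with an estimated correlation). Beside these stand the shares of mitochondrial counts, 12.6% to 14.1% in every knockout library but KO ZT16 replicate 2 (22.3%) and 16.3% to 22.4% in wild type. Without that library the medians were -0.38 and -0.77.

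**Figure D3:**
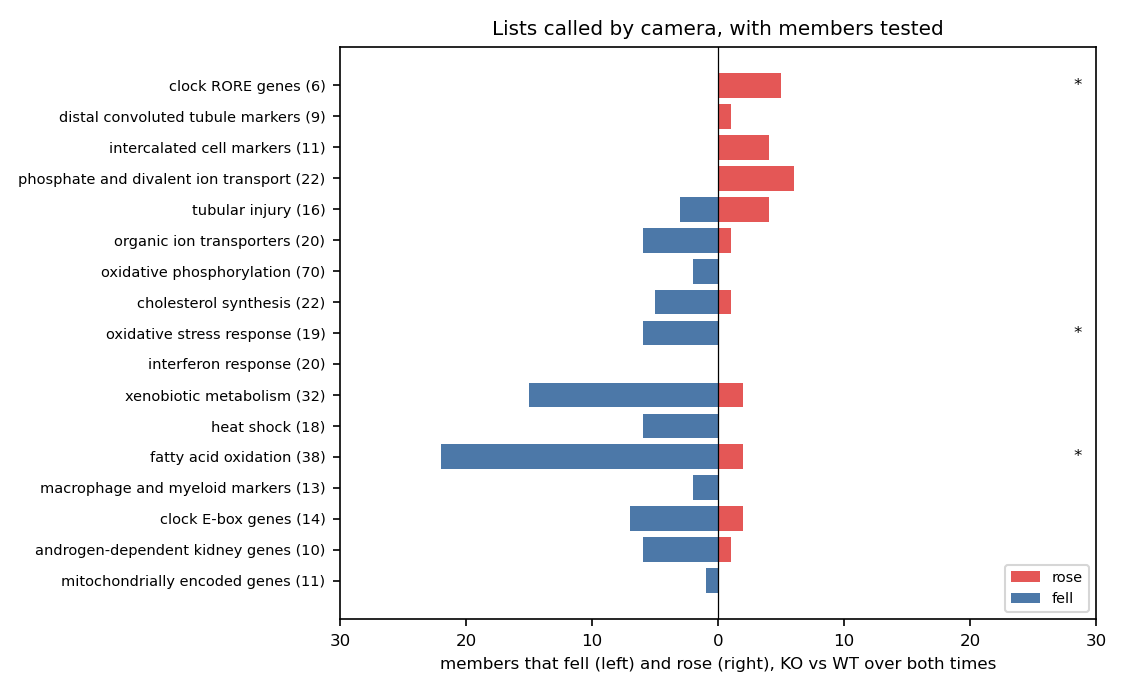
Number of members that rose (bars to the right) or fell (bars to the left) in the knockout over both times (x axis) in the 17 lists that camera called, with the number of members tested in brackets. An asterisk marks the 3 lists also called with an estimated correlation: clock RORE genes, fatty acid oxidation, with 22 members that fell, and oxidative stress response.

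Sugar, amino acid, sterol and ion genes changed in part over both times. Of 34 glycolysis and gluconeogenesis genes 2 rose and 6 fell (4 and 8 over the list alone, camera adjusted p = 0.171), with the glucose transporter genes Slc2a1 at 0.50 ± 0.07 and Slc2a2 at -0.39 ± 0.06. Of 24 NAD genes 3 fell (3 over the list alone, adjusted p = 0.171), among them Nampt, of the NAD salvage pathway (-0.64 ± 0.14), and the NAD synthetase gene Nadsyn1 (-0.25 ± 0.06). Of 38 arginine, urea and amino acid genes 7 rose and 9 fell (9 and 11 over the list alone, adjusted p = 0.86). These had Arg2, Ddc (0.94 ± 0.07) and Glud1, glutamate dehydrogenase (0.46 ± 0.05), up and Asl (-0.43 ± 0.06) and the transporters Slc7a13 (-0.64 ± 0.11) and Slc6a19 (-0.48 ± 0.09) down. Of 22 cholesterol synthesis genes 5 fell and 1 rose (10 and 1 over the list alone, adjusted p = 0.0131, or adjusted p = 0.532 with an estimated correlation, and adjusted p = 0.172 without KO ZT16 replicate 2). Insig1 was at -0.65 ± 0.12, squalene epoxidase Sqle at -0.49 ± 0.08 and Idi1 at 0.71 ± 0.10. Of 22 phosphate and divalent ion genes 6 rose (8 rose and 1 fell over the list alone, adjusted p = 0.00156, or adjusted p = 0.494 with an estimated correlation). Slc34a2 was at 1.58 ± 0.14, Slc20a2 at 0.38 ± 0.05 and the claudin gene Cldn19 at 0.41 ± 0.09. Of 17 water and urea genes 4 rose and 5 fell (6 and 5 over the list alone, adjusted p = 0.86). Avpr1a was at 0.85 ± 0.08 and the aquaporin genes Aqp11 and Aqp1 at -0.43 ± 0.07 and -0.31 ± 0.05.

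Of 18 heat shock genes 6 fell over both times (9 over the list alone, adjusted p = 1.51e-05, or adjusted p = 0.278 with an estimated correlation), including Hsph1 (-0.49 ± 0.10) and Dnaja1 (-0.42 ± 0.07). In the tubular injury list 4 of 16 rose and 3 fell (5 and 4 over the list alone). Fgg, Fgb (2.06 ± 0.18) and Cdkn1a, the gene of the cell cycle inhibitor p21 (1.53 ± 0.11), rose, and Havcr1 (-1.51 ± 0.22) and vimentin, Vim (-0.27 ± 0.06), fell. Camera called this list higher (adjusted p = 0.0047, or adjusted p = 0.494 with an estimated correlation) with a median of 0.06 and a mean of 0.27. Without Fgg and Fgb the other 14 members had a median of -0.13 (camera, unadjusted p = 0.921), so the call rested on these 2 genes. At ZT4 the median of the whole list was -0.15 while its mean was 0.18, so there the median and the test differed in sign. No member of the interferon list passed, though camera called it lower (median -0.21, adjusted p = 0.0185, or adjusted p = 0.649 with an estimated correlation), a call that ended without WT ZT4 replicate 1 (0.0854), KO ZT4 replicate 2 (0.054) or WT ZT16 replicate 1 (0.0728).

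Camera did not call the 9 other pathway lists over both times. Nuclear receptors and tubule regulators had 1 gene up, Ppard, and 1 down of 19 (adjusted p = 0.373), the tricarboxylic acid cycle 0 of 23 (0.159), fatty acid synthesis 1 up and 2 down of 17 (0.58), and sodium, potassium and chloride transport 1 up and 1 down of 34 (0.399). Glucocorticoid response had 1 up, Cdkn1a, and 2 down of 15 (0.481), cold-induced RNA-binding genes 0 of 5 (0.77), immediate early genes 1 up and 2 down of 20 (0.264), fibrosis and matrix 0 of 17 (0.926), and cell cycle 1 up of 20 (0.843).

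Cell type markers gave the following values over both times, which a whole-kidney library shows without telling cell number from expression per cell. Intercalated cell markers were called higher, with 4 of 11 rising (6 over the list alone, adjusted p = 0.0178, or adjusted p = 0.532 with an estimated correlation), including the bicarbonate transporter Slc4a9 (0.50 ± 0.08) and Kit (0.64 ± 0.14). Distal convoluted tubule markers were called higher with 1 of 9 rising (5 over the list alone, adjusted p = 0.0145, or adjusted p = 0.494 with an estimated correlation). Macrophage and myeloid markers were called lower with 2 of 13 falling (5 over the list alone, adjusted p = 0.00722, or adjusted p = 0.532 with an estimated correlation, and adjusted p = 0.0769 with length and GC offsets and KO ZT16 replicate 2 left out), including the receptor gene Csf1r (-0.33 ± 0.06). Androgen-dependent kidney genes had 6 of 10 falling and 1 rising (6 and 1 over the list alone, adjusted p = 5.46e-06, or adjusted p = 0.252 with an estimated correlation). Cyp2e1 was at -0.88 ± 0.08, Cyp4b1 at -0.66 ± 0.08, Gusb, beta-glucuronidase, at -0.56 ± 0.09 and Cyp2j13 at -0.56 ± 0.09, and Cyp7b1 at 0.58 ± 0.11.

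Camera called none of the other marker lists over both times. Proximal tubule S1 to S2 markers had 1 gene up, Gatm (0.33 ± 0.06), and 1 down, Slc6a19, of 10 (adjusted p = 0.594), S3 markers 1 up, Cyp7b1, and 3 down of 10 (0.275), thick ascending limb markers 1 down, Umod (-0.46 ± 0.10), of 9 (0.86), and collecting duct principal cell markers 2 up and 2 down of 11 (0.825), Tmem45b (-0.52 ± 0.11) among the latter. No member passed among podocyte (0 of 10, adjusted p = 0.224), endothelial (0 of 12, 0.416), stromal and smooth muscle (0 of 12, 0.331), lymphocyte (0 of 14, 0.373), adrenal cortex (0 of 3, 0.777), adipocyte (0 of 10, 0.693), red blood cell (0 of 8, 0.156) or sex-linked (0 of 4, 0.373) lists.

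Over both times 1834 genes passed (976 higher, 858 lower; 4599 at an unadjusted p under 0.05), 135 and 116 of them at least 2-fold, with a median absolute log2 fold change of 0.46. For 1415 genes (8.76%, chance 1%) library values of the genotypes overlapped at neither time. The count was 1137, 1177, 1212, 1120 and 1121 without WT ZT4 replicate 1 or 3 or KO ZT4 replicate 2, 4 or 6, in that order, 1153 and 1180 without WT ZT16 replicate 5 or KO ZT16 replicate 4, and 6935 without KO ZT16 replicate 2.

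The genotype effects at ZT4 and ZT16 shared no library and were compared across genes. All 338 genes called at both times had the same sign, 168 higher and 170 lower, where independent lists of these sizes share 5.46 and 5.24. Of the 531 genes called at ZT4, 98.3% had the same sign at ZT16, and of the 651 called at ZT16, 97.1% had the same sign at ZT4. Pearson's r of the log2 fold changes was 0.634 across 16150 genes, which are not independent replicates. From differences of mean log2 CPM it was 0.673, and of 200 label permutations within time only the real one reached it, the next highest r being 0.563.

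**Figure D4:**
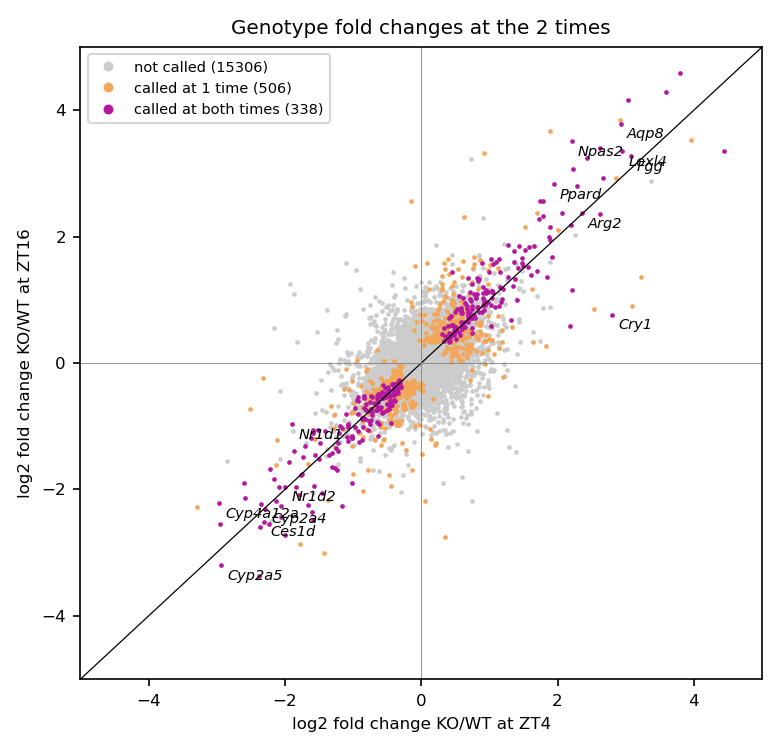
Log2 fold change of knockout over wild type at ZT16 (y axis) against ZT4 (x axis) for each tested gene, with the line of equal change. All 338 genes called at both times (purple) lie in the quadrants of equal sign, 506 were called at 1 time (orange), Cry1 lies far below the line, and 2 genes outside the axes are not drawn.

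The day-night difference in wild type was measured as the background for the genotype effects. Heat shock genes, which follow body temperature, were higher at ZT16, with 14 of 18 rising and none falling (15 over the list alone, adjusted p = 3.78e-27, and adjusted p = 0.0347 with an estimated correlation). Hspa1b rose by 2.49 ± 0.24, Hspa1a by 2.27 ± 0.31, Hspa8 by 1.26 ± 0.14, Dnaja1 by 0.99 ± 0.10 and Dnajb1 2.30-fold (SE of log2 0.13). Clock genes showed large changes, Per2 rising by 2.51 ± 0.19, Cry1 by 2.17 ± 0.15, Wee1 by 0.94 ± 0.15 and Per3 by 0.73 ± 0.13, and Nr1d1 (-2.70 ± 0.16) and Npas2 (-1.73 ± 0.19) falling. Arntl fell by 0.70 (adjusted p = 0.018), a call lost without WT ZT4 replicate 1 (0.0617) or WT ZT16 replicate 3 (0.0639). Over the alternatives for Arntl adjusted p ranged from 0.000462 to 0.0639. The RNA-binding protein genes Tra2a (1.01 ± 0.11) and Cirbp (-0.99 ± 0.16) changed in opposite directions.

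Metabolic and hormone genes also differed between the times in wild type. The vitamin D enzyme genes Cyp27b1, which makes the active hormone, and Cyp24a1, which degrades it, moved by 1.82 ± 0.26 and -1.22 ± 0.21. Pck1, of gluconeogenesis (1.47 ± 0.14), Alas1, which starts haem synthesis (1.47 ± 0.12), the mitochondrial carrier gene Slc25a25 (2.11 ± 0.26), Glul (0.76 ± 0.10), Nat8f5 (1.97 ± 0.28), Cyp2a5 (1.79 ± 0.31) and the sulfotransferase gene Sult1a1 (0.88 ± 0.15) rose. Glucocorticoid-induced genes Tsc22d3 (1.53 ± 0.15), Sgk1 (1.25 ± 0.19) and Fkbp5 (0.85 ± 0.14) rose, as did Egr2 (2.96 ± 0.44) and Ier3 (0.99 ± 0.14) of the immediate early list. Lrat, a retinol esterification enzyme gene (-1.87 ± 0.18), the diacylglycerol kinase gene Dgkg (-1.93 ± 0.21), the cationic amino acid transporter gene Slc7a2 (-1.24 ± 0.20), Col3a1 (-0.91 ± 0.12), Slc6a19 (-0.85 ± 0.13) and Ddc (-0.81 ± 0.10) fell.

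Camera called 14 of 42 lists between the times in wild type, and apart from heat shock each lost its call with an estimated correlation. Higher at ZT16 were immediate early genes (7 of 20 rose, 12 over the list alone, adjusted p = 2.96e-09, or adjusted p = 0.268 with an estimated correlation), xenobiotic genes (7 rose and 1 fell of 32, 13 and 1 over the list alone; 5.29e-08; 0.268) and RORE genes (3 rose and 1 fell of 6, the same over the list alone; 1.38e-06; 0.123). So were fatty acid oxidation (5 of 38 rose, 12 over the list alone; 0.000306; 0.268) and glucocorticoid response (3 rose and 1 fell of 15, 4 and 1 over the list alone; 0.00227; 0.122), the second p of each being that with an estimated correlation. Oxidative phosphorylation genes (none of 70 passed, over all genes or over the list alone; 1.09e-09; 0.514) and mitochondrially encoded mRNAs (1 of 11 rose, 2 over the list alone; 0.00611; 0.514) were higher with medians of 0.45 and 0.49, and the latter median turned to -0.10 with length and GC offsets. Fibrosis and matrix genes were lower (4 fell and 1 rose of 17, 11 and 1 over the list alone; 0.000306; 0.35). Calls that 1 left-out library ended were those of E-box genes (5 rose and 1 fell of 14, 7 and 1 over the list alone; 0.00227; 0.361; 0.0576 without WT ZT4 replicate 1), the tricarboxylic acid cycle (0 of 23; 0.0301; 0.268; 0.0845 without WT ZT16 replicate 1) and thick ascending limb markers (2 of 9 rose; 0.0111; 0.35; 0.0525 without WT ZT16 replicate 1), all higher. Lower were S1 to S2 proximal tubule markers (2 of 10 fell; 0.0114; 0.35; 0.07 without WT ZT16 replicate 3) and cell cycle genes (1 of 20 fell; 0.0296; 0.268; 0.0527, 0.0845 and 0.0888 without WT ZT4 replicate 1, WT ZT16 replicate 1 or KO ZT16 replicate 2).

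Between the times in wild type 1050 genes passed (463 higher at ZT16, 587 lower; 4737 at an unadjusted p under 0.05), 90 and 91 of them at least 2-fold, with a median absolute log2 fold change of 0.60, and library values did not overlap for 6874 genes (42.6%, chance 10%). The share of calls that were higher was 44.1%, and 33.3% with upper-quartile scaling. The count was 439, 621 and 220 without WT ZT4 replicate 1, 3 or 5, 441, 551 and 261 without WT ZT16 replicate 1, 3 or 5, 679, 657 and 639 without KO ZT4 replicate 2, 4 or 6, and 5473 without KO ZT16 replicate 2.

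The day-night difference in the libraries labelled knockout was tested in the same way. Cyp27b1 (2.30 ± 0.29) rose and Cyp24a1 (-2.12 ± 0.22) fell at ZT16, and the heat shock genes Hspa8 (1.24 ± 0.14), Chordc1 (1.08 ± 0.13), Dnajb1 (0.86 ± 0.13) and Dnaja1 (0.77 ± 0.10) rose. Of the clock genes Nr1d1 fell (-1.77 ± 0.17) and Per2 (1.09 ± 0.17) and Per3 (0.87 ± 0.14) rose, whereas Cry1 (0.13 ± 0.13, adjusted p = 0.482), Arntl (-0.19 ± 0.14, 0.336) and Npas2 (-0.43 ± 0.16, 0.0906) did not pass. Npas2 passed without KO ZT16 replicate 6 (-0.55, adjusted p = 0.0427). Creld2 and Manf, which encode secreted proteins induced by endoplasmic reticulum stress, rose by 1.59 ± 0.22 and 1.52 ± 0.20. Alas1 (1.37 ± 0.12), Slc25a25 (1.85 ± 0.26), Pck1 (0.92 ± 0.14), Tra2a (0.89 ± 0.11), Sult1a1 (0.86 ± 0.15) and Ehhadh, a peroxisomal beta-oxidation enzyme gene (0.73 ± 0.12), rose as well. Wipi1, of autophagy (-1.30 ± 0.16), Slc7a2 (-1.20 ± 0.21), Cirbp (-1.14 ± 0.16), Dgkg (-1.13 ± 0.20), the integrin gene Itga8 (-1.10 ± 0.09) and Col3a1 (-0.86 ± 0.12) fell.

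The mitochondrial ribosomal RNA genes mt-Rnr1 (1.41 ± 0.22) and mt-Rnr2 (1.69 ± 0.25) rose at ZT16 in the knockout, where the mitochondrial share of counts was 14.0% to 22.3% against 12.6% to 12.8% at ZT4. Camera called 13 lists there, of which none kept its call with an estimated correlation. Higher were heat shock (13 of 18 rose, 16 over the list alone, adjusted p = 1.74e-16, or adjusted p = 0.132 with an estimated correlation), oxidative phosphorylation (0 of 70, 37 over the list alone; 4.82e-09; 0.662) and xenobiotic genes (8 rose and 1 fell of 32, 16 and 1 over the list alone; 7.14e-07; 0.503). So were mitochondrially encoded mRNAs (2 of 11 rose, 10 over the list alone; 0.000158; 0.504) and fatty acid oxidation (9 of 38 rose, 12 rose and 2 fell over the list alone; 0.00386; 0.504), the second p of each being that with an estimated correlation. The call of mitochondrially encoded mRNAs ended with length and GC offsets (adjusted p = 0.895), their median turning from 0.74 to -0.04. Also higher were thick ascending limb markers (5 rose and 1 fell of 9, 6 and 1 over the list alone; 0.00972; 0.504), amino acid genes (4 rose and 1 fell of 38, 11 and 1 over the list alone; 0.0256; 0.5) and the tricarboxylic acid cycle (3 of 23 rose, 10 over the list alone; 0.0266; 0.5). Lower were fibrosis and matrix genes (4 of 17 fell, 11 fell and 1 rose over the list alone; 0.00025; 0.504) and podocyte markers (2 of 10 fell, 3 over the list alone; 0.00772; 0.553, and 0.159 with length and GC offsets). Calls of 3 higher lists ended without KO ZT16 replicate 2: tubular injury (1 of 16 rose; 0.0256; 0.662; then 0.11), androgen-dependent genes (1 of 10 rose; 0.0295; 0.662; then 0.0695) and adipocyte markers (0 of 10; 0.0404; 0.662; then 0.243). The last 2 calls also ended without KO ZT4 replicate 2 (0.0819 and 0.352) or KO ZT16 replicate 6 (0.062 and 0.129).

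Between the times in the knockout 1691 genes passed (851 higher at ZT16, 840 lower; 5862 at an unadjusted p under 0.05), 78 and 111 of them at least 2-fold, with a median absolute log2 fold change of 0.56, and library values did not overlap for 6994 genes (43.3%, chance 10%). The count was 1042, 1112 and 1037 without WT ZT4 replicate 1 or 3 or WT ZT16 replicate 1, 408, 181 and 213 without KO ZT4 replicate 2, 4 or 6, and 2878 and 3629 without KO ZT16 replicate 4 or 6. Without KO ZT16 replicate 2 it was 1309, and 1108 of the 1691 genes (65.5%) were among them. A fit of only these 6 libraries called 36 genes and lost Per2, Per3, Slc25a25, mt-Rnr1, mt-Rnr2, Slc7a2, Dgkg, Tra2a, Sult1a1, Ehhadh, Pck1 and Dnajb1 (adjusted p 0.0514 to 0.0737).

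The size of the day-night difference was compared between the genotypes. All 602 genes called in both genotypes changed in the same direction, where independent lists would share 54.9. Among the 1050 genes called in wild type the median absolute log2 fold change was 0.60 in wild type and 0.47 in the knockout, with 1023 of the same sign. Among the 1691 genes called in the knockout it was 0.42 in wild type and 0.56 in the knockout, with 1665 of the same sign. Choosing genes by their call in one genotype raises the value in that genotype, so the genotype in which genes were chosen had the larger value each time, and these medians show no difference in size between the genotypes.

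The interaction of genotype and time tested whether the genotype effect differed between ZT4 and ZT16, and 3 genes passed, each with adjusted p = 0.00134. The effect on Cry1 (ENSMUSG00000020038, chromosome 10, 85131700 to 85185064, minus strand) was lower at ZT16 by -2.04 ± 0.20. Cry1 had risen from ZT4 to ZT16 in wild type, from 3.67 ± 0.635 to 16.6 ± 1.70 CPM (SD), and lay above its wild-type ZT16 level at both times in the knockout, at 25.8 ± 2.27 and 28.3 ± 3.86 CPM. Stra6l, a relative of the retinol transporter gene Stra6 (ENSMUSG00000028327, chromosome 4, 45848664 to 45887008, plus strand), had an effect larger at ZT16 by 1.25 ± 0.12, with 32.27 ± 2.235 and 15.13 ± 0.3365 CPM in wild type at ZT4 and ZT16 and 40.53 ± 4.017 and 45.30 ± 0.8557 CPM in the knockout. The number passing was 8 without KO ZT16 replicate 2 and 5 without KO ZT16 replicate 4, and 540 genes had an unadjusted p under 0.05. With the replicate number as a block in edgeR, Cry1 (adjusted p = 0.122) and Stra6l (0.0771) lost their calls. Their estimates hardly moved (-2.05 and 1.25), and the block leaves fewer residual degrees of freedom.

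Other genes were not called for the interaction but passed in some alternatives. Per2 had -1.42 ± 0.25 (adjusted p = 0.245) and passed without KO ZT16 replicate 2 (-1.23, adjusted p = 0.00424) or replicate 4 (-1.61, 0.0459), with a range of 0.000373 to 0.981 over its alternatives. Npas2 had 1.30 ± 0.25 (adjusted p = 0.456) and passed without KO ZT16 replicate 2 (1.47, adjusted p = 0.00257), with a range of 0.000283 to 1. Egr2 had -3.10 ± 0.67 (adjusted p = 0.608) and passed with DESeq2 (adjusted p = 0.00461), with a range of 0.00461 to 1. Among the gene lists, the genotype effect on immediate early genes was called lower at ZT16 than at ZT4 (0 of 20, 12 lower over the list alone, median -0.86). Camera adjusted p was 6.29e-31, and 0.0278 with an estimated correlation, but 0.133 with fry. The genotype effect on RORE genes was called lower too (2 of 6 lower, 3 lower and 2 higher over the list alone, median -0.80). Camera adjusted p was 8.52e-15, and 0.0241 with an estimated correlation. The genotype effect on cell cycle genes was called higher (0 of 20, 1 over the list alone, median 0.27). Camera adjusted p was 2.69e-08, and 0.0241 with an estimated correlation. Camera called 9 lists in all. The genotype effect on E-box genes (0 of 14, 6 lower and 1 higher over the list alone, median -0.29) was called lower with adjusted p = 2.18e-06, or adjusted p = 0.287 with an estimated correlation.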

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

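Of the tests in this part, those on KO ZT16 replicate 2, on the mitochondrial lists, on Alb and on the other injury genes were chosen after the results were seen, and the test of other liver genes before.

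A test of the difference between the genotype effects at the 2 times called 3 genes and 9 lists. Of 100 drawn splits of the libraries 7 gave as many genes as the real 3 (highest other 4173). Such splits exchange genotype labels within each time and can turn a genotype effect shared by both times into an interaction. They therefore cannot decide whether chance gave that count, and chance is not excluded. The effect on Cry1 was lower at ZT16 by -2.0402 and that on Stra6l higher by 1.2533 (adjusted p = 0.00134 each by edgeR). Both calls were lost with the replicate number as a block (adjusted p = 0.122 and 0.0771). The estimates were then -2.0485 and 1.2548, and the block leaves fewer residual degrees of freedom. Median interactions of lists called by camera were -0.8588 for immediate early genes, -0.8019 for RORE genes, 0.2664 for cell cycle and -0.2924 for E-box genes, and of these E-box genes lost the call with an estimated correlation and with fry (adjusted p = 0.287 and 0.558), and immediate early genes with fry (0.133).

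The other 5 lists lost their calls with an estimated correlation, with fry and without single libraries. Adipocyte markers (median 1.3485) lost theirs without KO ZT4 replicate 2 (median 0.8779, adjusted p = 0.0677) or KO ZT16 replicate 2 (0.6264, 0.096). Heat shock (-0.0269) lost it without WT ZT4 replicate 5 (0.0512, median turning to 0.0461), KO ZT4 replicate 2 (0.0864), WT ZT16 replicate 5 (0.173, turning to 0.027), KO ZT16 replicate 2 (0.096) or KO ZT16 replicate 6 (0.0531). Glucocorticoid response (-0.2587) lost it without KO ZT16 replicate 2 (median -0.0982, 0.0889). S3 proximal tubule markers (0.2091) lost it without KO ZT4 replicate 2 (0.0864), WT ZT16 replicate 1 (0.0529), WT ZT16 replicate 3 (0.0565) or KO ZT16 replicate 2 (median 0.0981, 0.0797). Cholesterol synthesis (-0.0954) lost it without WT ZT4 replicate 5 (0.282), KO ZT4 replicate 2 (0.0657), KO ZT4 replicate 6 (0.0773), WT ZT16 replicate 1 (0.143), WT ZT16 replicate 3 (0.0876) or KO ZT16 replicate 2 (median -0.0342, 0.507).

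Among reads outside the gene counts, the share with no feature averaged 5.8558% in KO ZT4 and the ambiguous share 0.5298%, each above all 3 WT ZT4 libraries (4.38% to 5.10% and 0.466% to 0.494%). No biological explanation was tested.

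KO ZT16 replicate 2 stood apart from KO ZT16 replicates 4 and 6. A wild-type kidney under a knockout label is argued against by its position on the axis from wild-type ZT16 (0) to KO ZT16 replicates 4 and 6 (1) over the 531 genes called at ZT4, 0.8482. Each left out of its own end of the axis, replicates 4 and 6 lay at 0.967 and 0.992 and the wild-type ZT16 libraries between -0.04 and 0.05. Fitted to protein-coding genes, length and GC content explained 41.9% of its deviations. In a separate calculation over all tested genes, the length and GC offsets left an SD of 0.4688 (0.5614 before). That lay above the highest of the 9 libraries of other groups (0.3094), so this trend is argued against as the whole source. Without 101 adipose genes the SD was 0.5574, but so few genes can hardly move it, and the adipocyte median between the times in the knockout was 1.2102, or 0.3881 without this library, so admixed fat stays open. What set this library apart stays open, RNA quality and handling included.

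Oxidative phosphorylation and mitochondrially encoded genes were called lower in the knockout over both times, though at ZT16 the median of the first (-0.1133) turned to 0.0094 and 0.0209 without KO ZT16 replicate 4 or 6. With length and GC offsets the median of the first went from -0.1635 (MAD 0.0869) to -0.0657 (MAD 0.1105) and camera's adjusted p from 0.0017 to 0.0809, while with the offsets and KO ZT16 replicate 2 left out it was -0.1304 (adjusted p = 0.000176, 33 falling and 4 rising). That median lies within its MAD of 0.1864, so a lower level in the knockout and this trend cannot be told apart for these genes. Without KO ZT16 replicate 2 the median was -0.3821 and 58 of 70 genes fell, which argues against that library as the source. Mitochondrially encoded genes went from -0.5611 to -0.2281 with the offsets (MAD 0.1104, adjusted p = 0.0063), and -0.2066 (MAD 0.1121, adjusted p = 0.0473) with that library also left out. At ZT16 alone camera's call for them ended with the offsets (median -0.1495, adjusted p = 0.0792), and with that library also left out (-0.0971, 0.419). Over both times, without offsets, their call was lost with an estimated correlation (adjusted p = 0.494) and with fry (0.0521). A MAD taken over genes does not measure the spread between libraries. So whether the trend is their whole source stays open.

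Fibrinogen genes were higher in the knockout. Admixed liver is argued against by Alb, the most abundant liver transcript, which differed by -9.1557 CPM where Fgg differed by 123.8 CPM. Other liver genes, 13 tested of a list of 18, had a median of 0.1426 (MAD 0.3004), 3 rising and 3 falling. Those that rose were the more abundant Ttr (0.97, mean 109.5 CPM), Apoh (0.78, 24.3 CPM) and Apoc3 (0.61, 6.81 CPM). Those that fell, Serpinc1, F2 and Fetub, had means of only 2.00, 0.657 and 1.18 CPM. Apoa2 and Itih1, at 5.43 and 5.78 CPM, did not pass. A general injury programme stays open: the 14 other injury genes had a median of -0.1323 (camera, unadjusted p = 0.921), 2 rising and 3 falling, which decides nothing. A response of the tubule to the loss of BMAL1 is a candidate explanation that these data do not test.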

How the results depend on the processing

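Offsets for length and GC content, leaving out KO ZT16 replicate 2 and WT ZT16 replicate 5 together, the offsets without KO ZT16 replicate 2, voom with quality weights and leaving out libraries outside the compared groups were chosen after the results were seen.

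Counts of called genes moved by over 1.5 times as follows. At ZT4 (531) DESeq2 called 1061, adjusted p under 0.01 207, only the 6 libraries compared 2877, length and GC offsets 975, both libraries left out 3512, the offsets without KO ZT16 replicate 2 2561, and voom with quality weights 4755. At ZT16 (651) the same settings gave 1008, 309, 200, 1030, 3476, 3613 and 5520. Over both times (1834) adjusted p under 0.01 gave 736, both left out 6182, the offsets without KO ZT16 replicate 2 5742 and quality weights 7842. Between the times in wild type (1050) DESeq2 gave 2149, adjusted p under 0.01 209, only the 6 libraries 3557, the offsets 1735, both left out 3589, the offsets without KO ZT16 replicate 2 4505 and quality weights 4080. In the knockout (1691) DESeq2 gave 3705, adjusted p under 0.01 136, only the 6 libraries 36 and quality weights 5007. For the interaction (3) DESeq2 gave 18, the offsets 9, both left out 16, the offsets without KO ZT16 replicate 2 22 and quality weights 17.

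With 1 library left out the counts ranged from 228 to 2503 at ZT4, 380 to 5099 at ZT16, 1120 to 6935 over both, 220 to 5473 and 181 to 3629 between the times in wild type and knockout, and 3 to 8 for the interaction; the report names the libraries. Without KO ZT16 replicate 2 every gene called in each comparison other than time in the knockout was still called.

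The replicate block gave 229 genes between the times in wild type, 189 in the knockout and 1 for the interaction, and left 35 of 36 list calls as they were. Calls lost were those of Cry1 (adjusted p = 0.122, over all alternatives 4.75e-17 to 0.122) and Stra6l (0.0771, 3.07e-17 to 0.0771) for the interaction, and between the times Arntl in wild type (0.0556, 0.000462 to 0.0639) and adipocyte markers in the knockout (0.0522, 8.87e-05 to 0.662). Libraries of the same number did not deviate together (r across genes 0.0542, -0.0676 and -0.2663 in wild type, -0.0081, -0.0509 and -0.0029 in knockout). These values show no pairing by number, but deviations from means of 3 libraries cannot exclude one. The genotype comparisons share no numbers.

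The correlation of genotype effects between the times (0.6344) was 0.7865 for genes with a mean of at least 5 CPM and 0.5058 to 0.6303 with 1 library left out. The median absolute day-night change in the knockout over that in wild type, on genes called in wild type (0.7877), ranged from 0.5629 to 0.902 with 1 library left out. That choice of genes lowers it, and on genes called in the knockout the medians were 0.5566 in the knockout and 0.4244 in wild type.

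Of 5123 pairs of a called named gene and an alternative, 5094 kept the call and the direction, 29 lost the call and 0 turned. The genes were picked mostly for keeping their call, so this is no independent measure. Of 241 pairs for named genes not called, 220 stayed, 20 gained a call and 1 turned sign: Arntl at ZT4 to 0.0964 without WT ZT4 replicate 1 (-0.1879 to 0.0964 over libraries left out). Mitochondrially encoded genes between the times in wild type turned to -0.0953 with the offsets and -0.094 with the offsets without KO ZT16 replicate 2.

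List calls over the 6 comparisons fell from 89 to 12 with an estimated correlation and to 58 with fry. With an estimated correlation E-box genes went from 5 to 1, fatty acid oxidation from 5 to 2, heat shock from 6 to 1, immediate early genes from 4 to 1 and cell cycle from 3 to 1. Organic ion transporters (3), xenobiotic metabolism (5), the tricarboxylic acid cycle (2), oxidative phosphorylation (5), mitochondrially encoded genes (5), amino acid metabolism (1), cholesterol synthesis (3), phosphate transport (3), glucocorticoid response (2), tubular injury (4), fibrosis (2) and interferon (3) went to 0. With fry oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis and interferon went to 0, phosphate transport, glucocorticoid response, immediate early genes and tubular injury to 1, amino acid metabolism to 2, oxidative stress from 3 to 5, and water handling and cold-induced genes from 0 to 1. With the offsets oxidative phosphorylation, mitochondrially encoded genes and amino acid metabolism had 2, glycolysis 3 and interferon 1. With the offsets without KO ZT16 replicate 2 mitochondrially encoded genes and glycolysis had 3, amino acid metabolism 2, cholesterol synthesis 0, and sodium transport, glucocorticoid response, cell cycle and interferon 1. With both libraries left out amino acid metabolism had 2, and nuclear receptors, cholesterol synthesis and cell cycle 1. With 1 library left out the calls ranged from 0 to 3 for nuclear receptors and cholesterol synthesis, 0 to 2 for fatty acid synthesis, 0 to 1 for water handling, 1 to 2 for the tricarboxylic acid cycle and amino acid metabolism, 1 to 3 for glucocorticoid response and interferon, 2 to 5 for tubular injury and 1 to 4 for cell cycle.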

Other observations

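The tests in this part, on the segment around Arntl, on female-biased genes and on other splits of the libraries, were chosen before their results were seen and that of Y-linked genes after, while Prlr and Abcc3 are named outside the rule for named genes.

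A segment of other genotype carried along with the edited Arntl locus could change its neighbours. Of 150 tested genes within 10 Mb of Arntl 19 (12.7%) were called over both times, against 1804 of 15846 elsewhere (11.4%), an odds ratio of 1.1289 (95% interval 0.657 to 1.84, Fisher's exact test, p = 0.605). This shows no excess, and the interval leaves room for a small one.

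Of 10 androgen-dependent kidney genes 6 fell and 1 rose over both times (camera adjusted p = 5.46e-06, or 0.252 with an estimated correlation), and Slc7a12, which is higher in female kidney, rose, so a shift towards the female pattern may underlie both. The 4 other female-biased genes had a median of 0.8266 over both times, with Prlr, the prolactin receptor gene (1.60 ± 0.18), and Abcc3 (1.31 ± 0.17) called and Cyp4a14 (0.35, adjusted p = 0.5) and Kynu (0.22, adjusted p = 0.508) not. Camera gave these 4 genes an unadjusted p of 6.25e-05, or 0.0361 with an estimated correlation. The labels do not give the sex of the mice, but 4 Y-linked genes lay at 22.6429 CPM or more in all 12 libraries, which argues against an unequal sex. A hormonal effect of the knockout stays a hypothesis, and 4 genes are a small list.

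Other splits of the same libraries were counted against the real ones. At ZT4 1 of 10 splits, the real one with 531 genes, gave as many (highest other 0). For ZT16 against ZT4 it was 1 of 10 in wild type (1050, highest other 0) and 1 of 10 in the knockout (1691, highest other 0). At ZT16 3 of 10 splits gave as many as the real 651, and the highest other called 3391, with WT ZT16 replicates 1 and 5 and KO ZT16 replicate 2 against WT ZT16 replicate 3 and KO ZT16 replicates 4 and 6. Splits of 3 against 3 are too few for a share under 0.05. Over both times 3 of 100 drawn splits gave as many as the real 1834 (highest other 5302), a share under the 0.05 set beforehand. With 100 draws this share is uncertain, and some other splits called more genes than the real one. It therefore does not exclude chance. For the interaction 7 of 100 gave as many as the real 3 (highest other 4173), so chance is not excluded. These splits can turn a genotype effect shared by both times into an interaction, so they cannot decide on chance for that count. Splits at ZT16 and over both times that call several times the real count point to a structure of the libraries at ZT16 other than genotype.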
